A study of Neurospora crassa with 2 samples.

How the data were processed

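RNA was sequenced from mycelia of 2 Neurospora crassa genotypes, Δ3βG and Δ3βGΔncw-1, with 1 library each, after 20 h of preculture and 4 h in 1% cellobiose. Per the labels' protocols, mycelia were collected by filtration and frozen, total RNA was isolated with TRIzol and cleaned on RNeasy columns, and libraries followed standard Illumina protocols. Per the submitters' processing notes the tools were TopHat2 2.0.8b, HTSeq 0.5.4p2 and DESeq 1.5.1, with no role given for each. The genome build, the gene annotation, the read length and whether strand was used in counting are not given in the sources used here, so reads of overlapping and antisense genes may not be separated, and neither may reads of near-identical gene copies. The authors deposited RPKM values, 1 column per library, in a single table per the file headers. Each column was matched to its library by the sample identifier in its name, and 0 columns of values were left unused.

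The table held 9730 genes under locus tags. Of these, 9729 matched the reference gene table of assembly NC12, which was used for gene symbols, for which genes neighbour each other and for gene spans in the recovery of reads; 1 did not match, and 1118 had a symbol. Because the build behind the values was not stated, no coordinates are given. RPKM was 0 for 574 genes in Δ3βG and 629 genes in Δ3βGΔncw-1, and for 465 in both. The median RPKM was 14.4 and 11.6, and the RPKM summed to 472959 and 491870.

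Depth was recovered from the values, a step chosen after they had been seen. A gene's RPKM multiplied by its model length and the library's total is a whole number of reads. From the smallest steps between genes whose model equals the reference span, the totals came out as 20510798 and 20019350 reads. Of the genes above 0 in either library, 9264 matched the reference, and the unmatched gene could not be tried. With a tolerance of 1e-06 reads plus 1e-09 of the read number, all 9264 had a fitting model length. It was at least 50% of the span, and no more than the span, and gave whole reads in both libraries. For 7514 of these genes there was no other solution at any shorter length tried. Of 5989 genes that reached 10 RPKM in either library, 4978 had a single solution. Elsewhere the smallest solution of at least 50% of the span was used for intervals, which makes them wider. Recovered reads summed to between 94.8% and 100.5% of the total in Δ3βG and between 98.2% and 100.7% in Δ3βGΔncw-1, from the smallest and the largest solutions. The interval of each fold is the exact Clopper-Pearson interval at 95%, conditional on the summed reads of both libraries. Intervals of list medians are the central 95% of 1000 Poisson draws of the members' reads. Reads are not independent molecules, so all such intervals and the floor of 3 reads for a gene at 0 cover counting error only and hold no variation between cultures.

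The following were set before the data were examined. The measure was the log2 ratio of RPKM + 1, Δ3βGΔncw-1 over Δ3βG, which understates the change of low genes. Genes with at least 10 RPKM in either library were classed by a 2-fold size rule, with no p-value. A gene below 10 RPKM in 1 library passed only by its value in the other, which fixed its direction in advance. Gene lists were cellulases, lytic polysaccharide monooxygenases and cellobiose dehydrogenases, hemicellulases and accessory esterases, sugar transporters, regulators of plant cell wall degradation, other β-glucosidases, starch degradation, glycolysis and fermentation, gluconeogenesis and the glyoxylate cycle, folding and secretion in the endoplasmic reticulum, cell wall synthesis and cell wall proteins, conidiation and starvation markers, light response and carotenoid genes, heat shock and oxidative stress, the mat A idiomorph, and ribosomal proteins and glycoside hydrolases by symbol. Members with at least 1 RPKM in either library counted as measured, and the 4 deleted genes were left out of the lists. Each list's median was placed among those of 10000 random lists of the same size drawn within deciles of mean expression, which describes these libraries and is not a test of genotype. The genes named are the 4 deleted genes, the 12 highest and 12 lowest log2 ratios, the 5 highest RPKM of each library, the 4 members of each list with the largest absolute log2 ratio among those that reached 10 RPKM, and every cellulase, transporter and regulator. The lower lytic polysaccharide monooxygenase gene, gh10-4, NCU00852, acu-5, ccg-6, NCU05429, mfa-1 and the genes in the observations after the main results were named after their values had been seen. Lists that needed product names, among them the respiratory chain, the proteasome, transfer RNA ligases and transcription factors, were not run because the reference table used here pairs genes with symbols only, and the heterokaryon incompatibility list matched fewer than 3 genes.

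The alternatives tried were pseudocounts of 0.1 and 5 RPKM, minimum values of 5 and 50 RPKM and none, limits of 1.5-fold and 4-fold, centring on the median gene, scaling by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end), RPKM scaled to equal sums, lists of only members that reached 10 RPKM, and lists without their most extreme member. Added after the data were seen were a count of genes whose counting interval lay wholly past 2-fold and the 2-fold counts within lists relative to the median gene. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

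Read recovery, fold calls and list percentiles were tested on simulated data made from the expression levels of this comparison, and the other steps were not. Read recovery, simulated for 9729 genes with other, known library totals, was right for 100% of the genes with 1 solution, and the largest solution was right for 91.9% of the others. The simulated model lengths lay within the range searched, so the result for genes with 1 solution was fixed in advance. It cannot show how recovery fares where a gene model falls outside that range. Fold calls were simulated with the recovered library totals, an assumed noise between libraries and changes in 200 genes of the 9729. Of genes changed 2.5-fold, 92.5% were called in the right direction, as were 100% of those changed 4-fold or 8-fold. Of unchanged genes, 0% were called. These shares follow from the noise assumed, which 1 library per genotype cannot estimate. The changed genes were drawn from genes expressed above the 10 RPKM limit, and no shift of the median gene was simulated. Of 200 unchanged lists of 10 genes, 2.5% lay outside the central 95% of random lists, and 100% of 50 lists raised by 1 log2 unit lay above it, among 8076 genes.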

Results

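Transcript levels were measured by RNA sequencing in mycelia of 2 Neurospora crassa strains that had been precultured for 20 h in minimal medium and then held for 4 h in 1% cellobiose, the disaccharide released from cellulose. The Δ3βG strain lacks the β-glucosidase genes gh1-1, gh3-3 and gh3-4, whose products cleave cellobiose to glucose. The Δ3βGΔncw-1 strain also lacks ncw-1, which encodes a non-anchored cell wall protein. The comparison asks what the loss of ncw-1 does to gene expression in a strain that cleaves cellobiose poorly. The study's title states that the NCW-1 protein promotes cellulase production by way of cellobiose uptake. There was 1 library per genotype, so no difference has a replicate check and no test between genotypes was made. The values were RPKM (reads per kilobase of gene model, scaled to library size) for 9730 genes, with scaling to 20510798 reads in the Δ3βG library and 20019350 reads in the Δ3βGΔncw-1 library. Folds below are ratios of RPKM, and log2 ratios are of RPKM + 1 in Δ3βGΔncw-1 over Δ3βG. The 95% intervals given with them are exact intervals from recovered whole reads and cover counting error only.

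The level of ncw-1 followed the genotype labels. The RPKM of ncw-1 (NCU05137) was 435 in the Δ3βG library and 2.62 in the Δ3βGΔncw-1 library, 166-fold lower (95% interval 144 to 192). The β-glucosidase genes, deleted in both strains, were low in both libraries, with no library of an intact strain to set them against. The RPKM of gh1-1 (NCU00130) was 1.09 and 3.41 (3.14-fold higher, 2.26 to 4.41), that of gh3-3 (NCU08755) 0.637 and 1.02 (1.60-fold, 1.06 to 2.43) and that of gh3-4 (NCU04952) 0.342 and 0.350. Both genotype labels end in the letter a. In the Δ3βG library the mat A idiomorph gene matA-1 (NCU01958) and ccg-4 (NCU02500), the gene of the mat A pheromone precursor, were listed at 0. In the Δ3βGΔncw-1 library they had 15.4 and 87.9 RPKM. Set against an assumed floor of 3 reads in Δ3βG, these were 109-fold and 1260-fold higher. The exact 95% lower limits of the folds were 88.6 and 1025. These 2 genes were the only ones at 0 in 1 library and at 10 RPKM or more in the other. Of the 3 genes of the mat A idiomorph, matA-2 (NCU01959) was at 0 in both libraries and matA-3 (NCU01960) had 0 and 0.269 RPKM. The RPKM of mfa-1 (NCU16992), the gene of the mat a pheromone precursor, was 141 in Δ3βG and 35.0 in Δ3βGΔncw-1, 4.02-fold lower (3.72 to 4.35). The 2 libraries thus differed in mating-type transcripts as well as in ncw-1, which applies to every difference below; mfa-1 was looked up after the other values had been seen.

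Genes for the breakdown of cellulose had far higher RPKM in the Δ3βGΔncw-1 library. Of the 9 cellulase genes, 7 reached 10 RPKM in either library and all 7 were at least 2-fold higher. Of these, gh45-1 and gh7-2 were below 10 RPKM in Δ3βG, so the limit itself fixed their direction. The title's wording, read alone, gives the opposite direction for cellulase production, which was not measured here. Whether the study meant that direction cannot be told from the sources used here, so no conflict with its findings is claimed. The direction of these RNA values rests on the library labels and on the level of ncw-1. The cellobiohydrolase genes cbh-1 (NCU07340) and gh6-2 (NCU09680) went from 222 to 13724 RPKM (61.8-fold, 60.8 to 62.9) and from 136 to 15268 RPKM (112-fold, 109 to 116). Together they took 0.0846% of the reads in Δ3βG and 6.23% in Δ3βGΔncw-1. The other members past 2-fold were gh6-3 (NCU07190, 34.8 and 2725 RPKM), gh7-1 (NCU05057, 33.7 and 1778 RPKM), the endoglucanase gene gh5-1 (NCU00762, 15.7 and 979 RPKM), gh45-1 (NCU05121, 7.55 and 138 RPKM) and gh7-2 (NCU04854, 5.75 and 39.7 RPKM). Both remaining members were low, with 1.31 and 1.85 RPKM for gh6-1 (NCU03996) and 0.324 and 0.665 RPKM for gh7-4 (NCU05104), and their intervals included no difference. The median log2 ratio of the 8 measured cellulase genes was 5.78 (counting interval 5.71 to 5.84), at percentile 100 of 10000 random lists matched on expression, whose central 95% ran from −0.63 to 0.43.

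Lytic polysaccharide monooxygenase and cellobiose dehydrogenase genes, whose products cut cellulose by oxidation, were also higher in Δ3βGΔncw-1, at 11 of the 12 members that reached 10 RPKM. The RPKM of gh61-4 (NCU01050) was 40.9 and 3671 (89.7-fold, 82.7 to 97.3), that of gh61-3 (NCU02916) 13.4 and 1797, that of gh61-7 (NCU00836) 12.5 and 1518, and that of NCU07898 9.93 and 694. Members below 10 RPKM in Δ3βG, such as NCU07898, passed the limit only by being higher in Δ3βGΔncw-1. The exception among the 12 was NCU07974, with 41.7 RPKM in Δ3βG and 18.3 in Δ3βGΔncw-1, which was less than 2-fold lower relative to the median gene. The members below 10 RPKM in both libraries were not higher either. They were gh61-11 (NCU07520, 2.79 and 1.08 RPKM, 2.59-fold lower, 1.52 to 4.57), gh61-10 (NCU01867), gh61-8 (NCU03000) and cdh-2 (NCU05923, 3.17 and 2.96 RPKM). The other cellobiose dehydrogenase gene, cdh-1 (NCU00206), had 13.2 and 862 RPKM. The median log2 ratio over 16 members was 3.19 (3.07 to 3.33), at percentile 100, and 5.37 over the members that reached 10 RPKM. Hemicellulase and accessory esterase genes were higher as well, with all 16 of the members that reached 10 RPKM at least 2-fold higher. Many of the 16, such as gh11-2 and NCU08785, were below 10 RPKM in Δ3βG, so the limit itself fixed their direction. The list had a median log2 ratio of 3.44 (3.31 to 3.54) over 22 members, at percentile 100. The xylanase genes gh11-2 (NCU07225) and gh10-1 (NCU05924) had 2.98 and 1517 RPKM (509-fold, 406 to 646) and 10.6 and 840 RPKM (79.4-fold, 69.4 to 91.2). NCU08785 had 3.85 and 920 RPKM. Among the members below 10 RPKM, gh10-4 (NCU07130) had 3.10 and 0.747 RPKM and NCU00852 had 2.82 and 0 RPKM, both in the other direction. The fold of NCU04870, 816 with an interval from 375 to 2224, rested on 0.312 RPKM in Δ3βG against 254 RPKM.

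Most sugar transporter genes were higher in Δ3βGΔncw-1 too. Of 13 that reached 10 RPKM, 9 were at least 2-fold higher, 1 was at least 2-fold lower and 3 were neither. The cellodextrin transporter genes cdt-1 (NCU00801) and cdt-2 (NCU08114) had 121 and 2401 RPKM (19.8-fold, 19.3 to 20.3) and 476 and 7276 RPKM (15.3-fold, 15.1 to 15.5). Higher members also included NCU05853 (1038 and 5194 RPKM), NCU05897 (53.8 and 357 RPKM), NCU00988 (22.3 and 214 RPKM), NCU04963 (54.9 and 193 RPKM) and NCU06138 (3.78 and 29.7 RPKM). The glucose transporter gene hgt-1 (NCU10021) and NCU09287 were closer to the limit, at 2.29-fold and 2.11-fold. The lower member was NCU01633, with 42.6 and 7.83 RPKM (5.44-fold lower, 4.89 to 6.06). NCU02188 had 110 and 192 RPKM, NCU00821 349 and 539 RPKM, and NCU05627 11.7 and 13.3 RPKM, while NCU04537 (4.07 and 1.65 RPKM) and NCU06384 (0.762 and 0.250 RPKM) stayed low in both. The list had a median log2 ratio of 1.49 (1.46 to 1.53) over 14 members, at percentile 100, with random lists between −0.54 and 0.25.

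**Figure D1:**
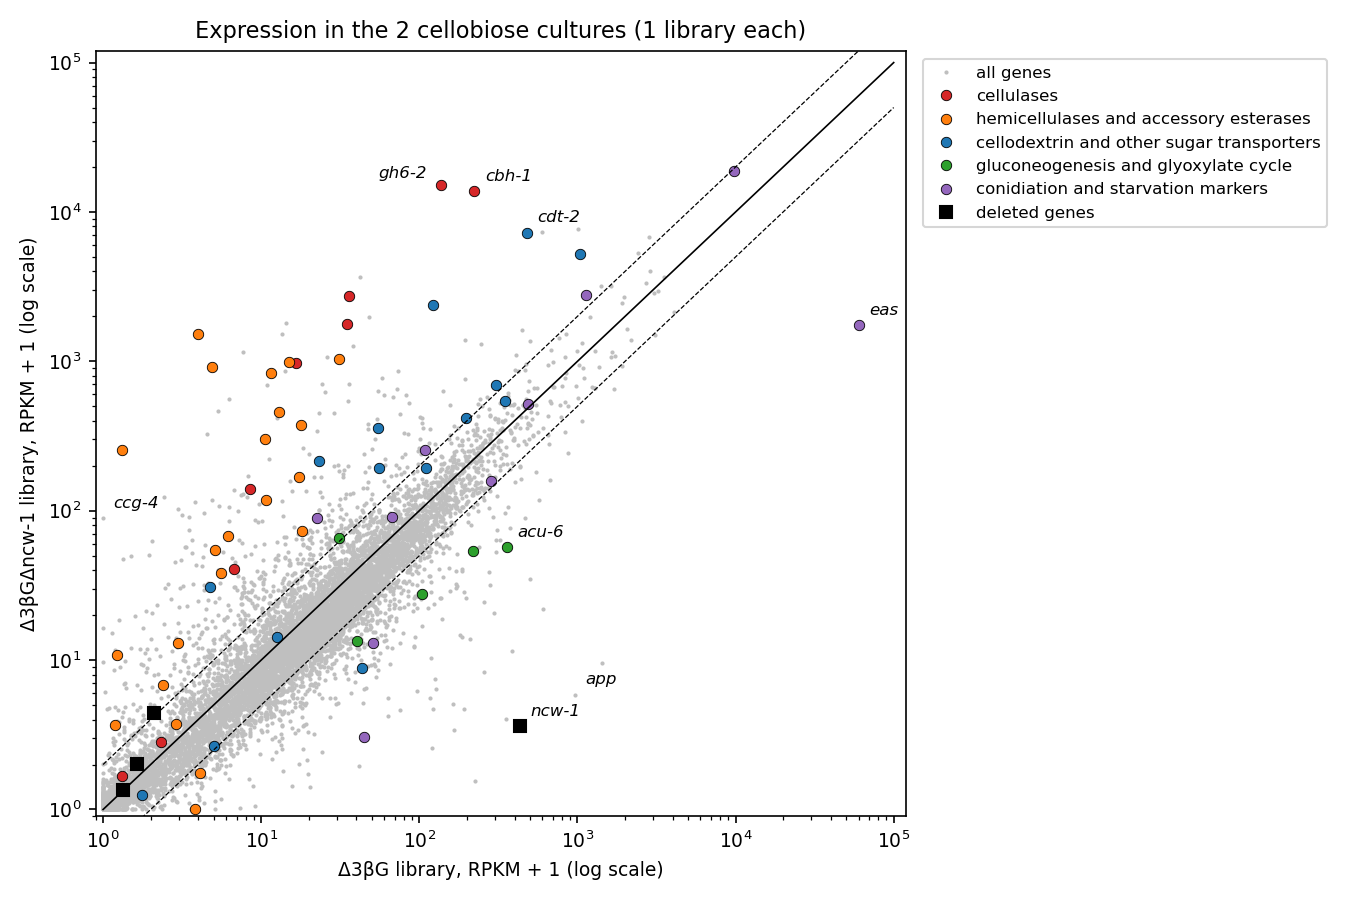
RPKM + 1 of each gene in the Δ3βG library (x axis, log scale) and the Δ3βGΔncw-1 library (y axis, log scale), with 5 gene lists coloured, the 4 deleted genes as black squares, the line of equal values (solid) and the 2-fold lines (dashed). Most cellulase, hemicellulase and transporter genes lie above the upper dashed line, up to 15268 RPKM for gh6-2, while eas lies far below the lower one at 60350 and 1746 RPKM.

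Among 8 regulators of plant cell wall degradation, 4 were at least 2-fold higher in Δ3βGΔncw-1 and 1 was at least 2-fold lower. The gene of the cellulase activator CLR-2, clr-2 (NCU08042), had 7.14 and 122.8 RPKM (17.2-fold, 15.7 to 18.9). The xylanase regulator gene xlr-1 (NCU06971) had 28.0 and 198 RPKM (7.08-fold), vib-1 (NCU03725) 29.96 and 184 RPKM (6.15-fold), and clr-1 (NCU07705) 45.3 and 111 RPKM (2.45-fold). The lower gene was cre-1 (NCU08807), which encodes the carbon catabolite repressor, with 66.3 and 11.04 RPKM (6.01-fold lower, 5.28 to 6.85). NCU01856 (137 and 190 RPKM) and NCU05255 (16.6 and 23.2 RPKM) were neither, nor was col-26 (NCU07788, 60.8 and 53.8 RPKM), whose log2 ratio of −0.17 turned to 0.15 under median centring and under trimmed mean scaling. The median log2 ratio was 0.87, at percentile 99.96, and 0.47 without clr-2.

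The β-glucosidase genes that were not deleted had a median log2 ratio of 0.89 over 4 members, at percentile 98.7. The highest was gh3-6 (NCU07487), with 6.68 and 1154 RPKM (173-fold, 156 to 192), followed by gh3-5 (NCU05577) with 31.4 and 69.6 RPKM (2.21-fold), while gh3-2 (NCU08054) had 27.5 and 28.0 RPKM, a log2 ratio of 0.026 that turned to −0.029 with RPKM scaled to equal sums. Of 6 starch degradation genes that reached 10 RPKM, 2 were higher and 1 was lower, with a median log2 ratio of 0.66 at percentile 99.5. NCU08746 had 10.1 and 222 RPKM and gh31-3 (NCU04674) 16.2 and 43.9 RPKM, whereas the glucoamylase gene gla-1 (NCU01517) had 186 and 39.5 RPKM (4.70-fold lower, 4.51 to 4.90). The remaining named member, gh31-1 (NCU09281), had 27.8 and 47.5 RPKM. Genes with a gh symbol, called glycoside hydrolases here, include the gh61 lytic polysaccharide monooxygenase genes and leave out cbh-1 and gla-1. Of 48 that reached 10 RPKM, 28 were higher and 2 were lower. Their median log2 ratio was 0.70 over 70 members, at percentile 100, and 1.68 over those that reached 10 RPKM. That limit keeps low genes that rose, such as gh3-6, and drops genes low in both libraries, so the larger median partly follows from it. This list shares members with several of those above.

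Genes of central carbon metabolism split by pathway. Of 11 glycolysis and fermentation genes that reached 10 RPKM, 4 were at least 2-fold higher in Δ3βGΔncw-1 and 7 were neither; relative to the median gene, 8 were higher and 3 were neither. The alcohol dehydrogenase gene adh-1 (NCU01754) had 140 and 636 RPKM (4.55-fold, 4.43 to 4.68), NCU00575 82.1 and 195 RPKM, the phosphoglycerate kinase gene pgk (NCU07914) 124 and 279 RPKM, and the aldolase gene fba (NCU07807) 265 and 575 RPKM. Their list had a median log2 ratio of 0.73, at percentile 99.9. Of 5 gluconeogenesis and glyoxylate cycle genes, 4 were at least 2-fold lower. The phosphoenolpyruvate carboxykinase gene acu-6 (NCU09873) had 356 and 56.0 RPKM (6.35-fold lower, 6.10 to 6.61), the malate synthase gene acu-9 (NCU10007) 218 and 52.8 RPKM, the fructose bisphosphatase gene fbp-1 (NCU04797) 103 and 26.7 RPKM, and the isocitrate lyase gene acu-3 (NCU04230) 39.1 and 12.5 RPKM. The higher member was acu-5 (NCU06836), which encodes acetyl-CoA synthetase, with 29.95 and 64.8 RPKM. The median log2 ratio was −1.90, at percentile 0.

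Conidiation and starvation markers went both ways. Of 10 conidiation and starvation markers, which stand for conidiating cells and starved hyphae in the culture, 3 were at least 2-fold higher, 3 were at least 2-fold lower and 4 were neither. The hydrophobin gene eas (NCU08457) had the highest RPKM of any gene in the Δ3βG library, 60350, and 1746 in the Δ3βGΔncw-1 library (34.6-fold lower, 34.2 to 34.9). The conidiation regulator genes acon-3 (NCU07617) and fl (NCU08726) had 43.9 and 2.07 RPKM (21.2-fold lower, 17.2 to 26.4) and 49.9 and 11.99 RPKM (4.16-fold lower, 3.84 to 4.51). The higher members were ccg-6 (NCU01418, 1132 and 2792 RPKM), NCU05429 (107 and 254 RPKM) and ccg-13; ccg-13 (NCU08907) had 21.7 and 88.3 RPKM (4.07-fold higher, 3.69 to 4.50). The list's median log2 ratio was 0.26, at percentile 96.2, while its mean was −0.58. Light response and carotenoid genes had a median of 0.17 at percentile 93.5, with 1 of 9 higher, 1 lower and 7 neither, and with 2 higher and 0 lower relative to the median gene. The first 2 were al-1 (NCU00552), the phytoene desaturase gene, with 32.7 and 120 RPKM, and al-3 (NCU01427), with 235 and 99.1 RPKM; bli-3 (NCU07267) had 464 and 881 RPKM and bli-4 (NCU08699) 9.51 and 13.5 RPKM.

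Among 10 heat shock and oxidative stress genes that reached 10 RPKM, 2 were at least 2-fold higher, the catalase gene cat-3 (NCU00355, 4.37 and 25.0 RPKM) and the superoxide dismutase gene sod-1 (NCU02133, 235 and 516 RPKM). The other 8 included hsp70-1 (NCU09602, 83.7 and 130 RPKM) and cat-1 (NCU08791, 81.6 and 120 RPKM), and the list's median log2 ratio was 0.31, at percentile 98.0. None of 8 genes for folding and secretion in the endoplasmic reticulum passed 2-fold, with 677 and 526 RPKM for the chaperone gene grp78 (NCU03982), 102 and 62.6 RPKM for NCU09485, and 449 and 512 RPKM for NCU09223. Their median log2 ratio of 0.052, at percentile 76.0, turned to −0.0041 with RPKM scaled to equal sums. Of 18 cell wall genes that reached 10 RPKM, 2 were higher, 2 were lower and 14 were neither. The higher pair was NCU09175 (410 and 1103 RPKM) and ncw-2 (NCU01752, 31.0 and 76.1 RPKM), and the lower pair acw-3 (NCU05667, 273 and 103 RPKM) and the chitin synthase gene chs-4 (NCU09324, 84.8 and 38.4 RPKM), of which only acw-3 stayed past 2-fold relative to the median gene. Their list's median log2 ratio was −0.52, at percentile 2.06, and −0.20 relative to the median gene. None of 7 cytosolic ribosomal protein genes passed 2-fold, with 94.7 and 66.3 RPKM for crp-5 (NCU04552), 19.3 and 13.1 for crp-3 (NCU07014), 32.6 and 22.8 for crp-4 (NCU04331) and 113 and 87.7 for crp-7 (NCU08627). Their median log2 ratio of −0.36, at percentile 39.8, lay −0.035 from that of the median gene.

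**Figure D2:**
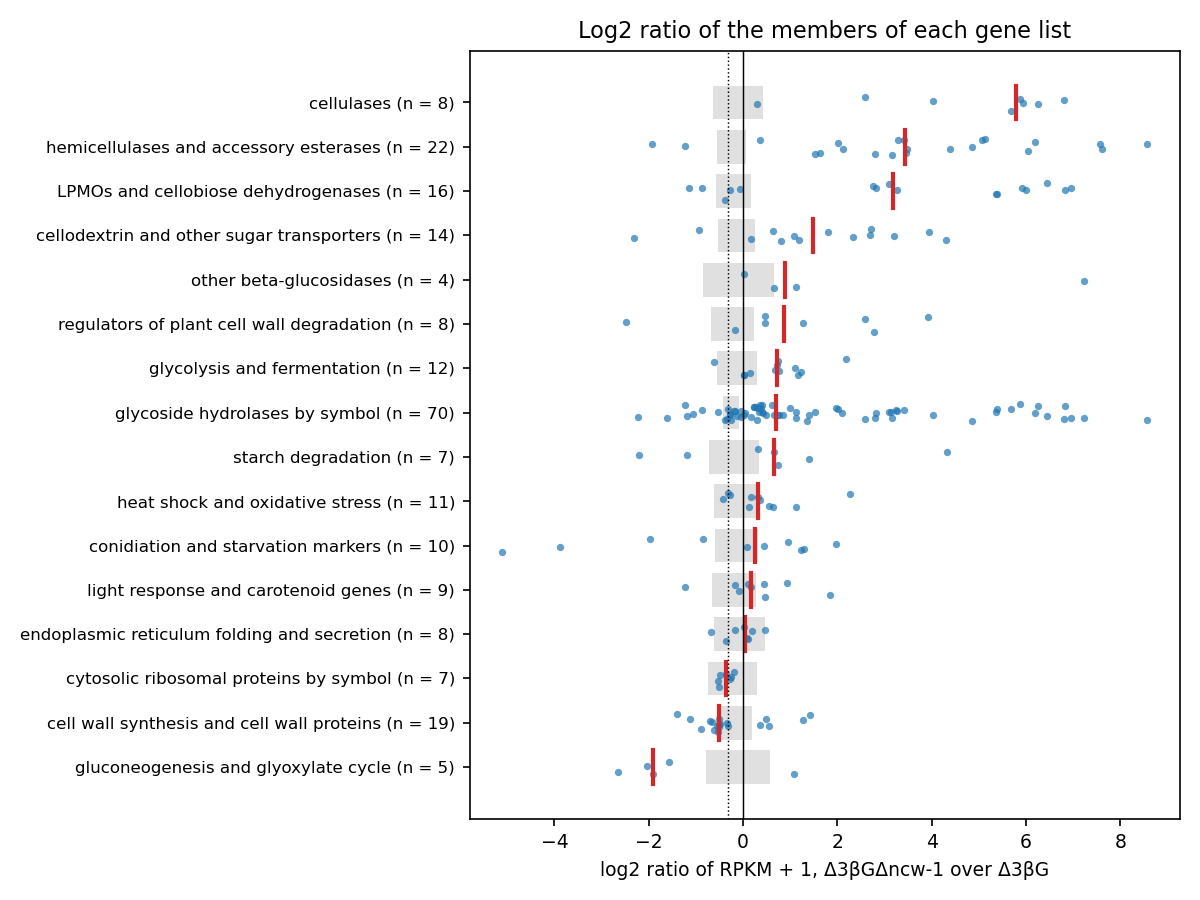
Log2 ratio of RPKM + 1, Δ3βGΔncw-1 over Δ3βG (x axis), for each member of a gene list measured at 1 RPKM or more (points, number of members in parentheses), with the list's median (red), the central 95% of the medians of 10000 matched random lists (grey), 0 (solid line) and the median gene at −0.32 (dotted line). The medians run from −1.90 for gluconeogenesis and the glyoxylate cycle to 5.78 for cellulases.

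The 12 genes with the highest log2 ratio included 9 of the cell wall degradation and transporter lists, among them gh11-2, gh3-6, gh61-3 and gh6-2, as did 23 of the 50 highest. The other 3 were ccg-4, NCU09764 (5.29 and 559 RPKM) and NCU09524 (4.32 and 462 RPKM). The 12 lowest held no member of those lists. Leaving out the deleted ncw-1, the lowest log2 ratio was that of app (NCU04533), which encodes an abundant perithecial protein, with 969 and 4.88 RPKM (199-fold lower, 162 to 246), followed by NCU09734 (1438 and 8.54 RPKM), NCU03011 (223 and 0.542 RPKM) and NCU00848 (353 and 3.06 RPKM). By the ratio of RPKM, without the added 1 RPKM, NCU03011 was further down than app, at 411-fold lower (274 to 649). Also among them were eas, the transcription factor gene ada-6 (NCU04866, 190 and 3.72 RPKM) and cut-1 (NCU04924, 163 and 4.12 RPKM), with NCU09210, NCU05858, NCU03451, NCU16512 and NCU00365 between 28.8-fold and 75.9-fold lower. In Δ3βG the genes with the highest RPKM after eas were ccg-1 (NCU03753, 9729 and 18716 RPKM), NCU16822 (4053 and 2126 RPKM), NCU05498 (3538 and 3671 RPKM) and the Woronin body gene hex-1 (NCU08332, 3247 and 2970 RPKM). The log2 ratio of hex-1, −0.13, turned to 0.19 under median centring and 0.20 under trimmed mean scaling, and that of NCU05498, 0.053, to −0.0034 with equal sums. In Δ3βGΔncw-1 the highest were ccg-1, gh6-2, cbh-1, NCU04522 (1002 and 7666 RPKM) and NCU08756 (593 and 7296 RPKM), which lies next to the deleted gh3-3.

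Across 5988 genes that reached 10 RPKM in either library, 484 were at least 2-fold higher and 664 at least 2-fold lower in Δ3βGΔncw-1, so 42.2% of these differences were toward higher values. At 4-fold or more, 204 were higher and 127 lower, and at 16-fold or more 59 were higher and 18 lower. The genes at least 2-fold higher took between 4.57% and 4.80% of the reads in Δ3βG and between 29.6% and 30.3% in Δ3βGΔncw-1, the ranges coming from genes with more than 1 possible read count. Those at least 2-fold lower, here with ncw-1 counted, took between 18.5% and 22.1% in Δ3βG and between 3.86% and 4.03% in Δ3βGΔncw-1. The median gene had a log2 ratio of −0.32, and relative to it 676 genes were at least 2-fold higher and 343 lower (66.3% higher); scaling by a trimmed mean gave 671 and 353 (65.5% higher). With RPKM scaled to equal sums, 464 were higher and 750 lower (38.2% higher). The balance of higher and lower genes therefore turned under median centring and trimmed mean scaling, but not with equal sums.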

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

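The alternative that used counting intervals and the counts within lists relative to the median gene were chosen after the data were seen; the others were set beforehand. No paired analysis was possible because there was 1 library per genotype. None of 649 alternative values changed the sign of a difference of at least 2-fold. For single genes this was fixed in advance. A pseudocount keeps the sign of a ratio, and the scalings shifted log2 ratios by far less than the 2-fold limit. It says nothing about variation between cultures. Of the 649 values, 300 stayed within the counting interval, or within 1.5 times for a count, and 349 moved beyond it. Of the list medians, 49 of 112 stayed within the interval, and only that of endoplasmic reticulum genes changed sign.

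The number of genes at least 2-fold higher in Δ3βGΔncw-1, 484, was between 419 and 676 under the other scalings, pseudocounts and lower minimum values. Genes at least 2-fold lower, 664, fell to 343 under median centring, 353 under trimmed mean scaling and 425 with a pseudocount of 5 RPKM. The first 2 settings raise every ratio, and the last one shrinks those of low genes. The number rose to 744 with a pseudocount of 0.1 RPKM, 750 with equal sums, 751 with a minimum of 5 RPKM and 844 with no minimum. By construction the counts also moved with a minimum of 50 RPKM (268 higher, 240 lower), a limit of 1.5-fold (752 and 1832) and a limit of 4-fold (204 and 127). With the counting interval wholly past 2-fold they were 453 and 554. Genes at a few reads, such as NCU04870 in Δ3βG, have wide intervals.

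The cellulase median, 5.78, was 6.10 under median centring, 6.10 under trimmed mean scaling, 5.55 with a pseudocount of 5 RPKM, 5.88 over members that reached 10 RPKM and 5.68 without its most extreme member. The transporter median, 1.49, was 1.81, 1.82, 1.45, 1.80 and 1.19 under the same settings, and 1.44 with RPKM scaled to equal sums. Other list medians moved by over 1.5 times: lytic polysaccharide monooxygenases from 3.19 to 5.37 and glycoside hydrolases from 0.70 to 1.68 over members that reached 10 RPKM, and regulators from 0.87 to 0.47 and conidiation markers from 0.26 to 0.44 without the most extreme member. Median centring moved conidiation markers to 0.58, heat shock genes from 0.31 to 0.63, light response genes from 0.17 to 0.49, endoplasmic reticulum genes from 0.052 to 0.37, cell wall genes from −0.52 to −0.20 and ribosomal protein genes from −0.36 to −0.035, and trimmed mean scaling moved the same lists alike. With equal sums light response genes were at 0.11. The limit of 10 RPKM in either library keeps low genes that rose and drops genes low in both libraries. The members it dropped from the lytic polysaccharide monooxygenase list all had negative log2 ratios. The larger medians over members that reached 10 RPKM therefore follow at least partly from the limit itself. Any further reason was not tested.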

Other observations

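The tests of symbol families, neighbouring genes and the 3 patterns below were chosen after the results they bear on had been seen, except that the glycoside hydrolase family is a list set beforehand. Gene families that share a symbol stem, 24 with at least 8 measured members, added groups that the fixed lists had not covered. The mus genes, named for sensitivity to mutagens and many of them used in DNA repair, had a median log2 ratio of −0.94 over 21 members, at percentile 0 of random lists matched on expression. Of the 16 that reached 10 RPKM, 9 were at least 2-fold lower in Δ3βGΔncw-1 and 1 was higher; relative to the median gene, 3 were lower and 1 was higher. Examples were mus-53 (27.9 and 7.04 RPKM in Δ3βG and Δ3βGΔncw-1), mus-11 (18.0 and 4.95 RPKM), and mus-51 and mus-52, which encode the Ku proteins of DNA end joining (29.5 and 10.8 RPKM, 28.6 and 12.7 RPKM). Members below 10 RPKM in Δ3βGΔncw-1, such as mus-53 and mus-11, passed the limit only by their Δ3βG value, so the limit itself fixed their direction. The peroxisome biogenesis genes (pex) had a median of −0.76 over 20 members, at percentile 0.06, and 5 were at least 2-fold lower. Relative to the median gene 2 were, pex3 (19.4 and 5.78 RPKM) and pex20 (12.7 and 3.41 RPKM). Both were below 10 RPKM in Δ3βGΔncw-1, so the limit fixed their direction too. The histone genes (hH) had a median of −0.71 over 9 members, at percentile 0.785, with 3 at least 2-fold lower, hH3 (3081 and 1506 RPKM), hH2B (1920 and 931 RPKM) and hH4-2 (830 and 335 RPKM), but 0 relative to the median gene. The medians of the mus, pex and hH genes relative to the median gene were −0.62, −0.44 and −0.39.

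The clock-controlled genes (ccg) had a median log2 ratio of 1.30 over 9 members, at percentile 99.98, and 6 of them were at least 2-fold higher; they overlap the conidiation list. Among the 6 was ccg-4, the mat A pheromone precursor gene, and eas, also known as ccg-2, is not counted under this stem. Without ccg-4 and with eas the median was 1.27 over 9 members, with 5 higher and 1 lower. Complex I genes (nuo) had a median of 0.20 over 29 members, at percentile 95.4, and none passed 2-fold. Of the 24 families, 4 lay below and 2 above the central 95% of random lists, among them the un genes at −0.79 and the glycoside hydrolases. Genes that differed lay next to each other more often than in random draws. There were 16 neighbouring pairs with both genes at least 4-fold lower, against a mean of 1.84 (central 95% 0 to 5) in 1000 draws, and 24 with both at least 4-fold higher, against 4.63 (1 to 9). Beside the deleted ncw-1, NCU05138 had 1.20 and 22.4 RPKM and the gene after it, NCU10883, 3.31 and 48.1 RPKM. There were 4087 neighbouring pairs with both genes at 10 RPKM or more in either library. Of these, 8 (0.196%), this pair included, had both log2 ratios at or above the lower one of this pair. The cut was set by the pair itself after its values were seen, so the small share is no test of its place beside ncw-1. The gene after NCU10883, NCU05141, was lower, with 125.8 and 84.9 RPKM. On the other side of ncw-1, NCU05136 had 232 and 318 RPKM, NCU05135 5.46 and 8.93 RPKM and NCU05134 5.84 and 29.9 RPKM.

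Transcripts of the mat A idiomorph in the Δ3βGΔncw-1 library, whose label carries the letter a, were the first pattern weighed. A candidate explanation is that the strain was mat A and that the letter is wrong or means something else. This needed less RNA of the mat a pheromone precursor gene, and mfa-1 had a log2 ratio of −1.98. Its RNA was not absent, however, with 35.0 RPKM left in Δ3βGΔncw-1. RNA of a mat A strain with intact ncw-1 could also have entered the library; at the ncw-1 level seen it would be at most 0.602% of the RNA if that strain expressed ncw-1 as Δ3βG did, and ccg-4 would then need 14610 RPKM in it. Since the profile of such a strain was not measured, that source stays open.

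The low RNA of eas, acon-3 and fl in Δ3βGΔncw-1 was the second pattern. Fewer conidiating hyphae in the culture would lower other conidiation genes too, but the con genes had a median log2 ratio of 0.076 and went apart, with con-6 1.81-fold lower (1.72 to 1.90), con-8 1.05-fold higher (1.03 to 1.08) and con-10 1.36-fold higher (1.25 to 1.48). With 3 such genes, whose RNA outside conidiating hyphae was not measured, the explanation stays open. A difference between the strains or cultures other than ncw-1, mating type included, cannot be told apart from the loss of ncw-1, because there was 1 library per genotype. The loss of ncw-1 itself stays open and untested for the same reason.

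The slight shift of most genes toward lower RPKM in Δ3βGΔncw-1 was the third pattern. The 4839 genes under 2-fold had a median log2 ratio of −0.30. Reads taken by the genes that differed at least 2-fold would shift all others by 1 amount, estimated as −0.15. That estimate used the largest possible read counts, and the smallest would give another value. In 4 equal groups by mean expression, from lowest to highest, the medians were −0.38, −0.33, −0.31 and −0.18, a difference of 0.205. The limit of 10 RPKM in either library can itself move the lowest group, since genes near it pass by their higher value. The remaining groups, from −0.33 to −0.18, also differed, which argues against those reads as the whole cause. What else lowered the low-expressed genes more was not tested, and no biological explanation was tested.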
